A study of Mus musculus with 2 samples.

How the data were processed

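Histone H3 trimethylated at lysine 36 (H3K36me3) is a chromatin mark that is laid down along the bodies of transcribed genes. It was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole intestine of mouse embryos at embryonic day 15.5. The labels give 1 group with 2 biological replicates, each a pool of tissue from many embryos of both sexes: 78 embryos for replicate 1 and 62 embryos for replicate 2. Each replicate was sequenced as 2 technical replicates, and the labels give a fragment size range of 300 to 500 bp. No second condition was part of the design, so the comparisons were those between the 2 replicates, between positions in and around genes, between groups of genes, and between chromosomes.

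The deposited files were 4 peak lists on the mouse build mm10. Per the file headers of the accompanying manifests, 1 list was called on replicate 1 alone, 1 on replicate 2 alone, and 1 on both replicates pooled, and a further list held the pooled peaks that the authors kept as replicated. Per the same manifests, the list of replicate 1 and the pooled list were derived from 2 control files each, and the list of replicate 2 from 1 control file. The peak caller, its version, its threshold and the rule behind the replicated list were not given in the sources used here. Each peak carried a fold enrichment over control, a ratio computed by the authors. Each peak also carried a −log10 p-value from the authors' caller, and the lowest deposited value was 2.01 in replicate 1 and 2.03 in replicate 2. These scores were used to describe, rank and filter peaks, to correlate the fold of overlapping peaks between replicates, to work back pileups as below, and to compare the highest fold of genes within replicate 1.

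Read counts and library sizes were not part of the peak lists. The pileup behind a peak could be worked back from its fold and p, taking the fold as (pileup + 1) / (background + 1) and p as the Poisson probability of a pileup above the whole part of the observed one. In replicate 1, 55343 of the 117201 peaks shared a background of 6.40 fragments, the floor of that list, and 100% of their summit pileups came out whole within 0.05. In replicate 2, 31440 of 73495 peaks shared a floor of 4.79 and 14.4% of pileups were whole within 0.05, as for pileups that had been scaled. The floor of replicate 2 was 0.749 times that of replicate 1. These floors were used in place of depth. If only replicate 2 was scaled, they are not a like measure of it, and the sequencing depth itself is unknown. At the floor, summit pileups had a median of 20 in replicate 1 and 17.0 in replicate 2, and the lowest listed were 13 and 11.6, so that marking below this height would not have been listed and a gene at 0% is one without a listed peak.

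Genes, exons, coding sequence and untranslated regions (UTRs) were taken from the GENCODE mouse annotation on GRCm38, the assembly equal to mm10, and assembly gaps and GC content from the RefSeq sequence of the same assembly. The number of peaks that ran past the end of their chromosome was 0 on the 21 chromosomes compared. A gene's covered share was the percent of its body, from annotated start to end, under the peaks of a replicate's own list, given as mean ± SD of the 2 replicates. Of 21911 protein-coding genes, 21196 had a body of at least 1 kb and were tested. A gene was called marked when at least 10% of its body was covered in each replicate. Peak bases were assigned to a single class in the order coding exon, UTR, non-coding exon, intron, promoter (1 kb upstream), downstream (5 kb) and intergenic. Profiles used 20 bins along genes of 10 kb or more and flanks of 5 kb. Peaks were held to be shared when they touched by 1 bp, and the chance value came from 100 shuffles of the peaks of replicate 2 within their chromosomes, outside assembly gaps. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Peaks next to each other are not independent, so these intervals are narrow.

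The 34 gene lists, the rule for named genes, the threshold of 0.05 and the tests were fixed before the data were examined. Each list's mean covered share was set against 10000 random lists of the same size, matched on gene length in 10 classes, with a two-sided permutation p and Benjamini-Hochberg adjustment over the 34 lists. Lists needed at least 5 members. This test compares a list with other genes in these libraries and not with another condition, and it treats member genes as independent. X-linked genes were compared with autosomal genes in the same manner. The genes named were the 4 members of each list with the highest mean covered share, plus up to 4 members marked in both replicates in each list called lower, of which there were 0, a set of 20 lineage genes and regulators fixed in advance, the 10 genes with the most bases under peaks in both replicates, the 5 genes per direction with the highest covered share in 1 replicate and 0% in the other, and the 5 widest regions of replicated peaks that touched no annotated gene. Members at 0% that the rule took only to fill up 4 are not all named.

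Alternative settings each changed a single choice, with the exception given below: a −log10 p of at least 5, the same number of top peaks in both replicates, 50% reciprocal overlap, shuffles within gene bodies, the authors' replicated or pooled list, each replicate alone, marking at 5% or 25%, genes of any length, genes of 3 kb or more for the profile, no overlapping genes, exons only, unmatched random lists, and the share of marked members. The authors' lists and each replicate alone are single lists. For the count of marked genes they therefore also dropped the need for coverage in each replicate. Merging peaks across gaps of 1 kb, and the stricter and the equal-sized peak sets for the agreement of peak strength, were added after the data had been seen.

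The calculations were made with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and plots with Matplotlib 3.10.9. The functions were tested on simulated data. With covered shares shuffled among genes of similar length, 1 of 340 random lists of 30 genes passed the threshold. With 10 percentage points added to 170 of the lists, 165 were called higher, and 6 of the other 170 were called. The shuffle kept to the length classes of the test itself, and lists with lowered coverage were not simulated. Interval functions disagreed with base by base counting in 0 of 1200 simulated peak comparisons. The profile returned 20 of 20 bins within 1 percentage point, and the pileup recovery returned 2547 of 2547 simulated floor peaks. The manifests were used only for the build, replicate numbers and control files, and the deposited q-values were not used here.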

Results

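H3K36me3 ChIP-seq peaks were analysed from whole intestine of mouse embryos at embryonic day 15.5, in 2 biological replicates of 1 group. The list of replicate 1 held 117201 peaks over 46.7 Mb, or 1.76% of the sequenced genome, and that of replicate 2 held 73495 peaks over 23.8 Mb, or 0.900%. Peaks were narrow, with a median width of 305 bp in replicate 1 and 262 bp in replicate 2, and the widest spanned 12865 and 8467 bp. The authors' fold enrichment had a median of 2.70 in replicate 1 and 2.95 in replicate 2 and reached 8.38 and 8.26. The background floor behind the peak calls was 6.40 fragments in replicate 1 and 4.79 in replicate 2, and the sequencing depth itself is unknown. All values given as mean ± SD are over these 2 replicates (n = 2).

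The first comparison asked how far the 2 tissue pools carried the mark at the same places. Of the replicate 2 peaks, 70.0% (51478 of 73495, 95% Wilson interval 69.7 to 70.4%) touched a replicate 1 peak, against 3.53 ± 0.0739% (SD of 100 shuffles) by chance within chromosomes and 7.79% by chance within gene bodies. Of the replicate 1 peaks, 40.6% (40.3 to 40.9%) touched a replicate 2 peak. The 14.3 Mb covered in both made up 30.7% of the replicate 1 bases and 60.2% of the replicate 2 bases, and 25.5% of the union. Replicate 1 peaks without a partner were narrower than those with one, at a median of 266 against 411 bp, and weaker, at a median fold of 2.57 against 2.84. With overlap required over 50% of both peaks, the share of replicate 2 peaks with a partner was 30.9%.

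Agreement was weak for the height of single peaks and close for whole genes. The fold of overlapping peak pairs had a Spearman rho of 0.194 across 51478 pairs, while the covered share of genes had a Spearman rho of 0.905 and a Pearson r of 0.925 across 21196 protein-coding genes. Each replicate 2 peak was paired with the strongest replicate 1 peak that it touched, and peaks without a partner were left out. The gene values included 10170 genes without a peak base in either replicate, so the 2 rhos are not like measures. These are correlations across peaks or genes, which are not independent replicates. Of the 3370 genes marked in replicate 2, 98.2% were marked in replicate 1 as well, while 3311 of the 5564 genes marked in replicate 1 were marked in replicate 2.

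**Figure D1:**
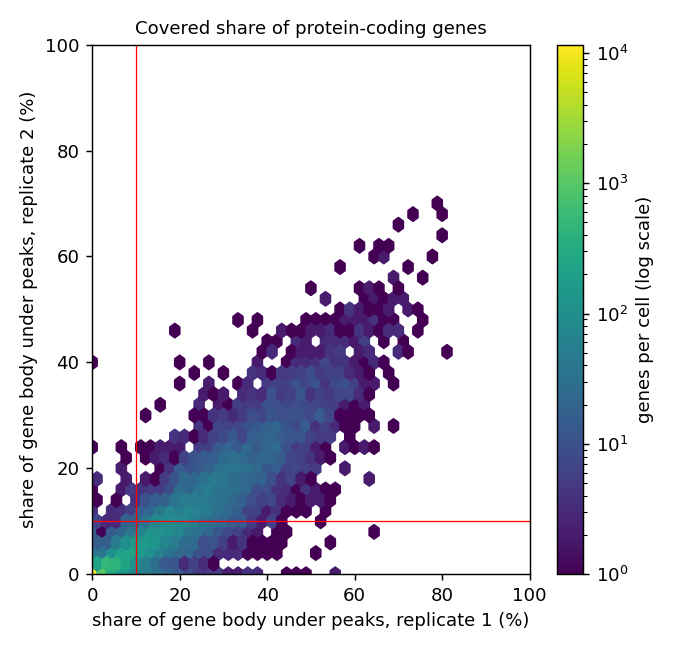
Covered share of 21196 protein-coding genes in replicate 1 (x axis, %) and replicate 2 (y axis, %), as counts of genes per hexagon on a log colour scale, with red lines at the 10% needed for a gene to be called marked. The mean covered share was 7.89% in replicate 1 and 4.33% in replicate 2, and 10170 genes lie at 0% in both.

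The authors' pooled list held 137356 peaks, of which 65695 (47.8%, 95% Wilson interval 47.6 to 48.1%) were in their replicated list, each with the same position and values. Peaks kept as replicated were wider and stronger than the rest, with medians of 474 against 234 bp and of 2.74 against 2.26 for the fold. Of 43713 pooled peaks that touched a peak of both single-replicate lists, 42905 were kept. A further 22790 kept peaks did not touch both of those lists, so the authors' rule was not plain overlap with them. Among pooled peaks with a −log10 p of at least 5, 76.4% were kept.

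The second comparison asked where the mark lay with respect to genes. Gene bodies, 46.0% of the sequenced genome, held 95.9 ± 0.239% of peak bases. Coding exons held 15.6 ± 1.67% of peak bases, 11.3 ± 1.21 times their share of the genome, UTRs were 5.10 ± 0.103 times and introns 1.59 ± 0.0454 times over-represented. Introns still held 65.6 ± 1.87% of peak bases because of their size. Promoters within 1 kb upstream of genes were depleted, at 0.120 ± 0.00766 times their genome share, as were the 5 kb downstream of genes at 0.628 ± 0.0107 times. Intergenic sequence beyond these flanks is 46.9% of the genome and held 0.348 ± 0.167% of peak bases. Each of these ratios lay on the same side of 1 in both replicates.

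Along genes, coverage rose from start to end. In 14149 protein-coding genes of 10 kb or more, the first 5 of 20 bins of the body were covered for 2.38 ± 1.09% and the last 5 bins for 9.89 ± 4.07%, and the ratio of last to first was 4.05 in replicate 1 and 4.36 in replicate 2. The first bin was covered for 0.379 ± 0.172%, and the highest coverage fell in bin 19, at 10.5 ± 4.39%. Coverage in the first kilobase past the annotated gene end was 7.11 ± 3.06%, against 0.263 ± 0.116% in the last kilobase before the gene start. In the fifth kilobase out it was 3.76 ± 1.61% past the end and 2.66 ± 1.13% before the start. Neighbouring genes were not removed from these flanks, so coverage there can belong to other genes. Within these genes, exons were covered for 11.4 ± 4.48% and introns for 2.51 ± 1.21%, a ratio of 4.65 ± 0.453. In windows of 300 bp, centred on exons or free of exons, the ratio was 6.09 ± 0.703. When such windows were compared within the same segment of 5 bins of the same gene, it was 1.66 ± 0.0947.

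**Figure D2:**
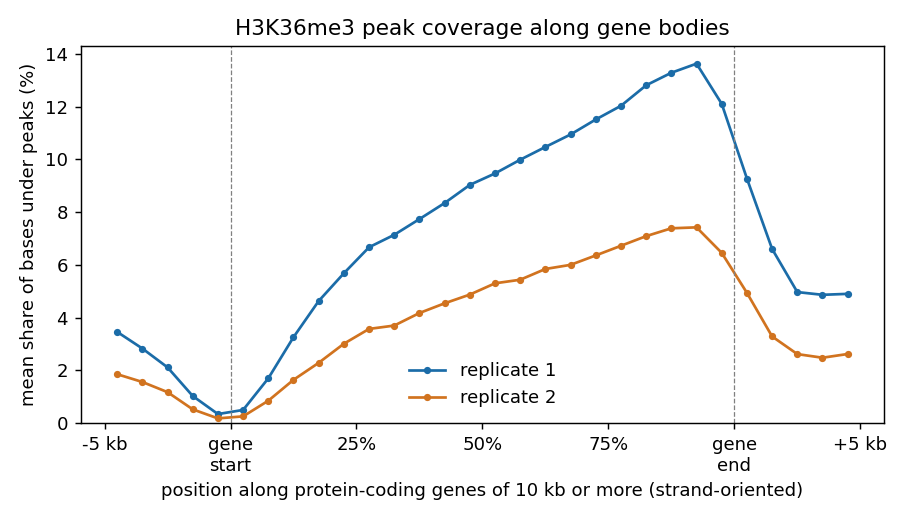
Mean share of bases under H3K36me3 peaks (y axis, %) in 20 bins along 14149 protein-coding genes of 10 kb or more and in 1 kb bins over 5 kb flanks (x axis), as a line per replicate. Coverage was lowest around the gene start and highest in bin 19 of both replicates, at 13.6% in replicate 1 and 7.42% in replicate 2.

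Replicated peaks, merged across gaps of 1 kb, formed 32207 regions on the assembled chromosomes, of which 1035 (3.21%) touched no annotated gene. Of these, 935 lay within 5 kb of a protein-coding gene, 911 of them past its end. The widest 5 included a region of 4.60 kb on chromosome 4 (119270769 to 119275365), 2.62 kb past the end of Ybx1, a DNA- and RNA-binding protein gene. A region of 4.05 kb on chromosome 2 (76624730 to 76628781) lay 1.12 kb past the end of Prkra, and one of 3.61 kb on chromosome 11 (120585975 to 120589579) lay 2.54 kb past the end of Alyref, an mRNA export factor gene. The others were 3.61 kb on chromosome 5 (104582232 to 104585841), 59.6 kb from the nearest protein-coding gene, BC005561, and 3.32 kb on Y (90739075 to 90742391), 12.1 kb from Gm21860.

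The third comparison asked which genes carried the mark. Of 21196 protein-coding genes, 3311 (15.6%) were marked in both replicates and 10170 (48.0%) had no peak base in either. The count of marked genes depended on the peak set and on the rule of 2 replicates. It was 1519 for peaks at a −log10 p of at least 5. It was 6423 for the authors' pooled list, a single list in which coverage in each replicate was not required. Replicate 1 alone gave 5564. Of the 3311 marked genes, 1814 overlapped another annotated gene, whose marking cannot be separated from theirs without strand. Among all 21196 tested genes, 10016 overlapped another gene. Marked genes had a median length of 16.4 kb and the others 19.3 kb. Among the 10 genes with the most bases under peaks in both replicates, Ubr4, a ubiquitin ligase gene (chromosome 4, 139352609 to 139489588), was covered for 49.2 ± 16.6% of 137 kb. Dync1h1, the heavy chain of the dynein motor (chromosome 12, 110601452 to 110666945), was covered for 54.0 ± 9.52%. The chromatin regulators Chd2, Trrap and Smarca4 were covered for 36 ± 8.01%, 48.6 ± 17.1% and 42.9 ± 13.5%, the transcription factor gene Gtf2i for 48.0 ± 8.54%, the non-muscle myosin gene Myh9 for 40.5 ± 6.46% and the ubiquitin ligase gene Nedd4 for 40.6 ± 11.0%. The others, Gm20388 and Fgfr2, are annotated over 4435 and 2961 kb across many other genes and were covered for 5.54 ± 2.58% and 2.51 ± 1.35%.

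The lists of spliceosome, cell cycle, ribosomal, proteasome and complex I genes were covered more than random lists. The list of spliceosome genes was covered for 31.3 ± 8.95% on average against 7.68% in length-matched random lists, with 25 of 30 members marked. Among them, Prpf8, the core factor of the spliceosome (chromosome 11, 75486816 to 75509449), was at 62.2 ± 8.68%, Snrnp70 at 54.4 ± 7.89%, Snrpa at 54.0 ± 9.82% and Snrnp200 at 53.0 ± 14.7%. Cell cycle genes were covered for 25 ± 8.07% against 7.47%, with 27 of 33 marked, among them Cdk4 (chromosome 10, 127063534 to 127067920) at 48.8 ± 5.69%, the replication helicase gene Mcm2 at 46.8 ± 12.1%, the mitotic kinase gene Aurka at 42.2 ± 18.1% and Cdk1 at 38.4 ± 0.453%. Cytosolic ribosomal protein genes were covered for 19.9 ± 4.58% against 4.21%, with 46 of 79 marked. Rps5 (chromosome 7, 12922290 to 12926686) was at 60.6 ± 11.0%, Rps3 at 48.8 ± 1.10%, Rpl27 at 46.9 ± 1.09% and Rpl23 at 46.0 ± 0.720%. Proteasome genes were covered for 18 ± 5.75% against 6.70%, with 27 of 49 marked, led by Psmc4 at 48.6 ± 9.59%, Psmd3 at 48.0 ± 13.6%, Psmc1 at 44.8 ± 4.46% and Psmd7 at 40.2 ± 15.2%. Genes of mitochondrial complex I were covered for 14.5 ± 6.84% against 6.43%, with 19 of 46 marked, led by Ndufb8 at 41.0 ± 12.7%, Ndufs7 at 36.6 ± 13.0%, Ndufa10 at 32.5 ± 15.6% and Ndufv1 at 31.3 ± 19.1%.

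The genes that write, read and erase H3K36 methylation were themselves covered for 16.7 ± 6.86% against 5.77%, with 15 of 28 marked and all 28 holding peak bases in both replicates. The demethylase gene Kdm4a (chromosome 4, 118136957 to 118180043) was at 52.3 ± 12.7%, the elongation factor gene Supt6 at 44.5 ± 9.51%, Brpf1 at 40.2 ± 14.6% and Hdgfl2 at 24.7 ± 8.71%. Setd2, which encodes the main H3K36 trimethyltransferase (chromosome 9, 110532597 to 110618633), was at 15.8 ± 5.28%. Zinc finger genes with Zfp symbols were covered for 12.4 ± 3.72% against 7.51%, with 134 of 397 marked. Their leading members were among the most covered of all genes named here, with Zfp110 (chromosome 7, 12834761 to 12850577) at 71.4 ± 3.53%, Zfp869 at 66.4 ± 13.5%, Zfp606 at 63.9 ± 4.21% and Zfp335 at 62.2 ± 16.5%. All 7 of these lists were higher than random lists, with an adjusted permutation p of 0.000425, which rests on the smallest raw p the permutations can give, 1e-04. Each mean was higher than that of the matched lists in both replicates alone. Without genes that overlap another gene, 5 of the 28 members of the H3K36 methylation list remained, and the list was higher than random lists by 9.69 percentage points, against 10.9 with all members, with an adjusted permutation p of 0.0648.

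**Figure D3:**
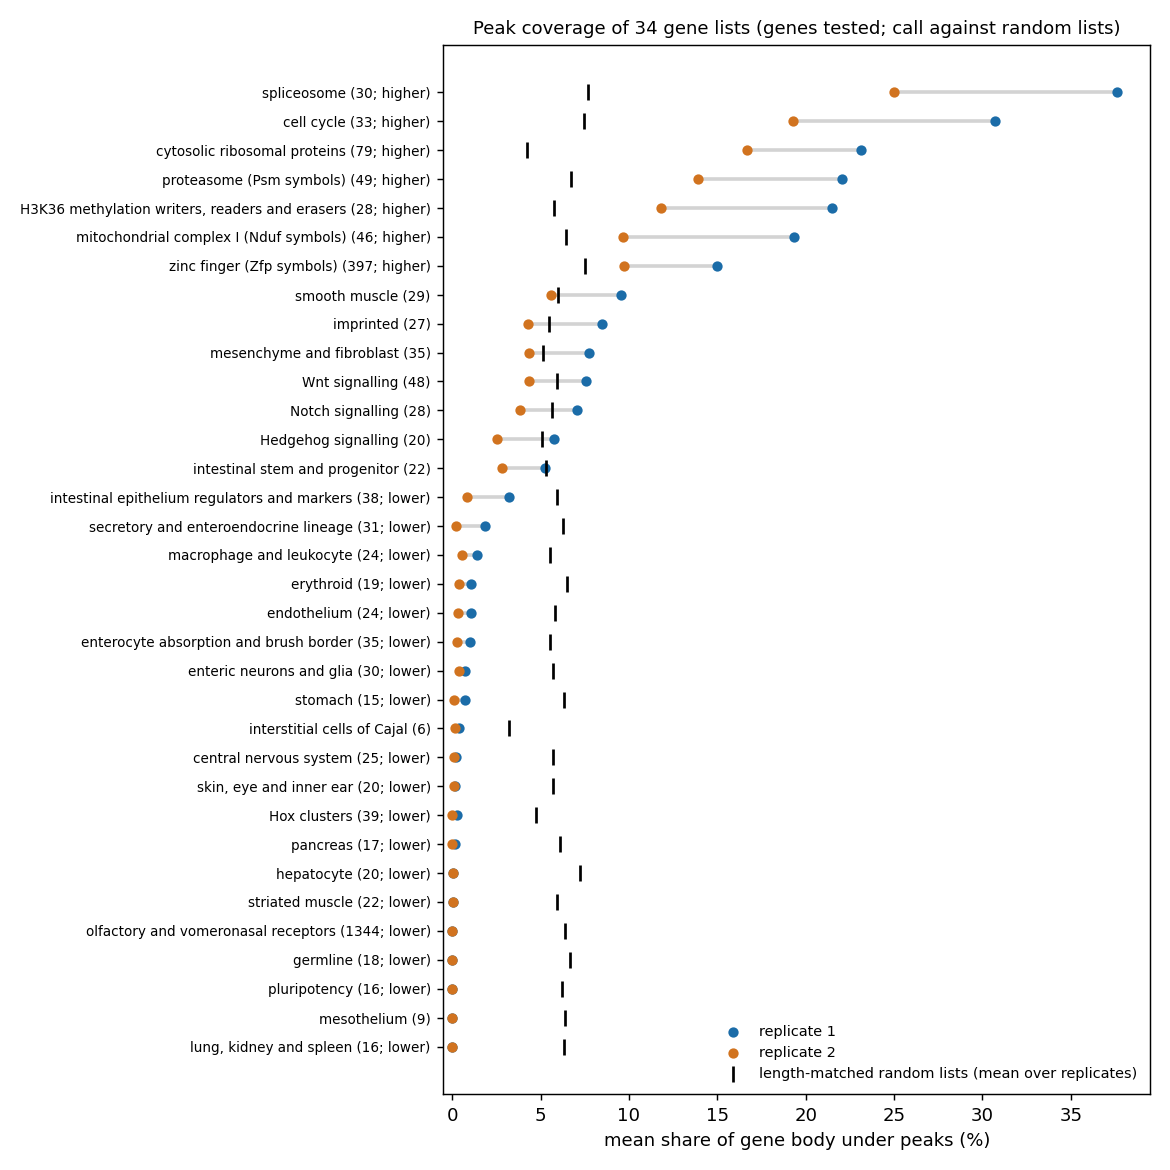
Mean share of the gene body under peaks (x axis, %) for 34 gene lists (y axis, with the number of genes tested and the call against length-matched random lists), with a point for each replicate and a black tick for the mean of the random lists. Lists called higher lie to the right of their ticks, up to 37.6% for spliceosome genes in replicate 1, and lists called lower lie to the left.

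Genes of the intestinal epithelium carried little of the mark in whole intestine. The list of epithelial regulators and markers was covered for 2.03 ± 1.67% against 5.95% in matched lists (adjusted permutation p = 0.0312, 38 genes). In this list 0 members were marked, against 15.6% of all tested genes. No peak base was held by 14 of the 38, against 48.0% of all tested genes. Its members thus lacked peaks no more often than other genes, and their peaks covered little of their bodies. Esrp2, an epithelial splicing regulator gene (chromosome 8, 106130319 to 106136974), was at 27.5% in replicate 1 and 9.77% in replicate 2, and its end overlaps Nfatc3. Krt18 was at 15.2% and 0%. The adhesion molecule gene Epcam (chromosome 17, 87635979 to 87651129) was at 5.79 ± 3.59%, Muc13 at 4.57 ± 3.27% and the villin gene Vil1 at 4.00 ± 1.51%. The transcription factor genes Cdx2, Gata4 and Sox9 were at 0% in both replicates, Hnf4a was at 2.86% and 0%, and the signal gene Shh at 1.94% and 0%. Genes of enterocyte absorption and the brush border were covered for 0.640 ± 0.554% against 5.55% (adjusted permutation p = 0.0151, 35 genes), with the peptidase gene Anpep highest at 4.32 ± 2.89%, then Myo1a at 2.14 ± 0.968%, Cdhr5 at 2.14 ± 3.02% and Cdhr2 at 2.02 ± 0.868%. Secretory and enteroendocrine genes were covered for 1.04 ± 1.15% against 6.24% (adjusted permutation p = 0.0186, 31 genes), and 28 of the 31 had no peak base. Most of their coverage was in the ghrelin gene Ghrl (chromosome 6, 113716119 to 113719880), at 51.6% in replicate 1 and 4.78% in replicate 2, which overlaps other annotated genes whose marking cannot be separated from its own. Creb3l1 was at 4.02 ± 2.61%, Dclk1 at 0% and 0.0661% and Agr2 at 0%.

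By mean covered share, genes of stem and progenitor cells and of the smooth muscle and connective tissue layers lay near other genes of their length. Their medians were lower than their means, at 0.789% for stem and progenitor, 2.65% for smooth muscle and 1.97% for mesenchymal genes. Among all tested genes, 48.0% had no peak base. Stem and progenitor genes were covered for 4.03 ± 1.71% against 5.30% (adjusted permutation p = 0.60, 22 genes). The 3 marked members were the Wnt feedback gene Axin2 (chromosome 11, 108920349 to 108950783) at 19 ± 9.05%, Ephb3 at 15.7 ± 3.15% and Msi1 at 13.1 ± 4.30%, and Cdca7 was at 12.4 ± 4.34%. Smooth muscle genes were covered for 7.57 ± 2.77% against 5.96% (adjusted permutation p = 0.470, 29 genes), with 6 marked. Smoothelin, Smtn (chromosome 11, 3517523 to 3540612), was at 32.2 ± 7.71%, the transcription factor gene Srf at 31.4 ± 6.15%, Tpm1 at 30.8 ± 7.74% and Pdlim7 at 25.5 ± 2.87%. The contractile genes Acta2 and Myh11 were at 3.91 ± 1.73% and 0.872 ± 0.965%. Mesenchymal genes were covered for 6.03 ± 2.38% against 5.13% (adjusted permutation p = 0.634, 35 genes), with 6 marked. The collagen genes Col6a1 (chromosome 10, 76708792 to 76726168), Col6a2 and Col1a1 were at 41.2 ± 15.7%, 21.7 ± 8.57% and 18.3 ± 6.02%, Fbln1 at 17.1 ± 6.88%, Pdgfra at 4.07 ± 0.0508% and the transcription factor gene Foxf1 at 5.85% and 0%. A p above the threshold does not show that these lists equal other genes.

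Of the signalling lists, none passed the threshold. Hedgehog genes were covered for 4.15 ± 2.30% against 5.09% (adjusted permutation p = 0.705, 20 genes), with the receptor gene Ptch1 (chromosome 13, 63508328 to 63573598) at 24.7 ± 6.94% as the only marked member, and Smo, Kif7 and Gli1 at 7.64 ± 5.01%, 7.35 ± 2.97% and 7.16 ± 5.65%. Wnt genes were covered for 5.98 ± 2.28% against 5.95% (adjusted permutation p = 0.986, 48 genes), with Dvl2 at 47.0 ± 15.5%, Dvl3 at 43.0 ± 10.6%, Gsk3a at 39.8 ± 17.6% and the beta-catenin gene Ctnnb1 at 28.8 ± 4.44%. Of the 48 Wnt genes, 25 had no peak base, near the share of 48.0% among all tested genes. Notch genes were covered for 5.46 ± 2.27% against 5.67% (adjusted permutation p = 0.941, 28 genes), with Ncstn at 35.4 ± 8.93%, the receptor gene Notch1 at 22.4 ± 4.38%, Maml1 at 14.7 ± 4.95% and Psen1 at 14.3 ± 4.55%. Imprinted genes were covered for 6.39 ± 2.97% against 5.49% (adjusted permutation p = 0.700, 27 genes). Their 4 marked members were Nnat at 50.2 ± 19.8%, which lies inside Blcap, Cd81 at 18.6 ± 9.07%, Igf2r at 18.5 ± 6.80% and Zrsr1 at 17.3 ± 0.724%, which lies inside Commd1.

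Of the lists of enteric neurons and glia, endothelium, erythroid cells, leukocytes, interstitial cells of Cajal and mesothelium, the first 4 were lower than random lists and the others did not pass the threshold. Genes of enteric neurons and glia were covered for 0.554 ± 0.232% against 5.68% (adjusted permutation p = 0.0159, 30 genes), with Tbx3 at 8.06 ± 0.262%, Erbb3 at 5.28 ± 2.66%, S100b at 5.21% and 0%, Ednrb at 0.752% and 0%, and Ret and Phox2b at 0%. Endothelial genes were covered for 0.700 ± 0.502% (adjusted permutation p = 0.0244, 24 genes), with Egfl7 at 6.05 ± 3.27%, Eng at 3.14 ± 0.531%, Mmrn2 at 2.51 ± 2.63%, Ets1 at 1.92 ± 1.12% and the receptor gene Kdr at 0.427% and 0%. Erythroid genes were covered for 0.744 ± 0.486% (adjusted permutation p = 0.0312, 19 genes), with the transferrin receptor gene Tfrc highest at 8.62 ± 3.54%, Nfe2 at 7.92% and 0%, Epb42 at 1.48 ± 0.00369%, Sptb at 0.158% and 0%, and Gata1 at 0%. Macrophage and leukocyte genes were covered for 0.988 ± 0.584% (adjusted permutation p = 0.0373, 24 genes). Their highest member, Cx3cr1 at 7.47 ± 1.86%, is annotated over 168 kb across other genes. Cd68 was at 10.9% and 0%, Fcer1g at 3.99 ± 1.14%, Csf1r at 3.91 ± 1.51% and Ptprc at 0%. Genes of interstitial cells of Cajal, the gut pacemaker cells, were covered for 0.244 ± 0.160% (adjusted permutation p = 0.178, 6 genes), with Ano1 at 0.857 ± 0.455%, Kit at 0.485 ± 0.335%, Etv1 at 0.239% and 0%, and Hcn1 at 0%. The 9 mesothelial genes were at 0% in both replicates against 6.41% in matched lists (adjusted permutation p = 0.0626).

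Markers of other organs were near 0%. Hepatocyte genes were covered for 0.0470 ± 0.0164%, pancreas genes for 0.0636 ± 0.0899%, stomach genes for 0.416 ± 0.431%, striated muscle genes for 0.0287 ± 0.0201%, central nervous system genes for 0.141 ± 0.0765%, and skin, eye and inner ear genes for 0.131 ± 0.0663%. Lists of lung, kidney and spleen, of the germline and of pluripotency held no peak base in either replicate. The albumin gene Alb and the pancreatic regulator gene Ptf1a were at 0%. In the hepatocyte list Cps1 was at 0.557 ± 0.216% and Trf at 0.768% and 0%, in the pancreas list Cela2a was at 2.16% and 0%, and in the striated muscle list Ttn was at 0.520% and 0%, Ryr1 at 0.205 ± 0.0499% and Neb at 0.167 ± 0.0246%. The stomach list held peak bases in Tff1 at 7.60% and 0% and in Muc6 at 2.45 ± 1.09%. The central nervous system list held them in Bcl11b at 2.47 ± 0.427% and Mbp at 2.10% and 0%, and the skin, eye and inner ear list in Pde6b at 2.29 ± 0.853% and Myo15 at 0.667% and 0%. The 39 Hox genes were covered for 0.128 ± 0.163%, with Hoxd10 highest at 5.47% and 0%, then Hoxb3 at 2.10% and 0%, Hoxd3 at 0.701 ± 0.294% and Hoxa3 at 0.982% and 0%, and 1342 of 1344 olfactory and vomeronasal receptor genes held no peak base, the exceptions being Vmn2r53 at 0.424% and Olfr56 at 0.142% in replicate 1. All of these lists were lower than random lists, with adjusted permutation p from 0.000425 for the receptors to 0.0451 for the stomach.

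In all, 7 lists were higher, 18 lower and 9 not past the threshold. Of the 18 lower lists, 1 stayed past it, that of the receptors, when genes that overlap another gene were left out, and 8 did so at a −log10 p of at least 5, while all 18 means stayed below those of the random lists in both settings. In replicate 2 alone 12 of 18 were past the threshold. Those that were not stayed below their random lists, as for erythroid genes at 0.40% against 4.64% and pancreas genes at 0% against 4.39%.

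The fourth comparison asked whether any cell type or neighbouring organ moved with one of the 2 tissue pools. Over all genes the covered share was 7.89% in replicate 1 and 4.33% in replicate 2. After that difference was subtracted, which favours lists with high coverage, spliceosome genes differed most, by a further 9.10 percentage points (37.6% against 25%), followed by cell cycle genes by 7.86, H3K36 methylation genes by 6.15 and complex I genes by 6.11. When both lists were cut to the same number of peaks, the excess of spliceosome genes was 4.49 percentage points. As a ratio, replicate 2 over replicate 1, all genes were at 0.549, and spliceosome and cell cycle genes lay above that value, at 0.664 and 0.628, so that their direction relative to all genes turned with the scale. H3K36 methylation genes were at 0.549 and complex I genes at 0.50. Among cell types, smooth muscle genes were at 0.589, mesenchymal genes at 0.564, enteric neuron genes at 0.544, leukocyte genes at 0.410, erythroid genes at 0.368, endothelial genes at 0.327, epithelial genes at 0.266, enterocyte genes at 0.241 and secretory genes at 0.122. The secretory ratio rested on Ghrl, which overlaps other genes, and was 0.382 without it, at 0.196% and 0.0748%. Other lists of low coverage had both low and high ratios, at 0.0521 for Hox genes, of which 35 of 39 held no peak base, 0.445 for central nervous system genes and 0.605 for hepatocyte genes. With a single library on each side these differences have no test. Of the neighbouring organs, stomach genes were at 0.721% in replicate 1 and 0.112% in replicate 2, a ratio of 0.155, hepatocyte genes at 0.0586% and 0.0355%, and pancreas genes at 0.127% and 0%. No peak base was held by 13 of 15 stomach, 18 of 20 hepatocyte and 16 of 17 pancreas genes, so each value rested on few genes. Tff1 and Cela2a, the highest of the stomach and pancreas lists, overlap another gene.

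The genes with the highest covered share in a single replicate were short. Sap25 at 56.3%, Lenep at 55.5%, 1700029I15Rik at 49.2%, Mus81 at 46.4% and Rep15 at 43.9% were covered in replicate 1 and at 0% in replicate 2, and the first 4 of these overlap another gene. In the other direction, Krtcap3 was covered for 39.9%, U2af1l4 for 23.3%, Rhbdl1 for 18.2%, Rps17 for 17.4% and Ldlrad2 for 16.1% in replicate 2 and 0% in replicate 1, and U2af1l4 and Rhbdl1 overlap another gene. Their lengths ran from 1.51 kb for Krtcap3 to 6.06 kb for Mus81, so that 1 or a few peaks made up each value. In the authors' replicated list, Sap25 was covered for 57.6%, 1700029I15Rik for 37.6%, Mus81 for 21.7%, Rep15 for 11.1% and Lenep for 4.26%. Rps17 was covered there for 26.8%, Ldlrad2 for 14.4% and U2af1l4 for 13.6%, and Krtcap3 and Rhbdl1 for 0%. A gene at 0% in 1 replicate could thus hold peaks that the authors kept as replicated.

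The fifth comparison was between chromosomes. X-linked genes were covered for 0.429 ± 0.319% against 5.97% in length-matched autosomal genes (two-sided permutation p = 1e-04, the smallest the permutations can give, 877 X-linked genes). X lay below every autosome in both replicates, at 0.654% and 0.203%, and 1 of its 877 genes was marked, against 16.4% of 20156 autosomal genes. Autosomes ranged from 4.34 ± 1.94% on chromosome 14 to 8.41 ± 3.47% on chromosome 8, and these were the lowest and the highest autosome in each replicate. All 163 genes of Y were at 0%, with 5 peaks on Y in each replicate. Peaks on X numbered 465 in replicate 1 and 152 in replicate 2, and the difference from autosomes was past the threshold in each of the 6 alternatives run.

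**Figure D4:**
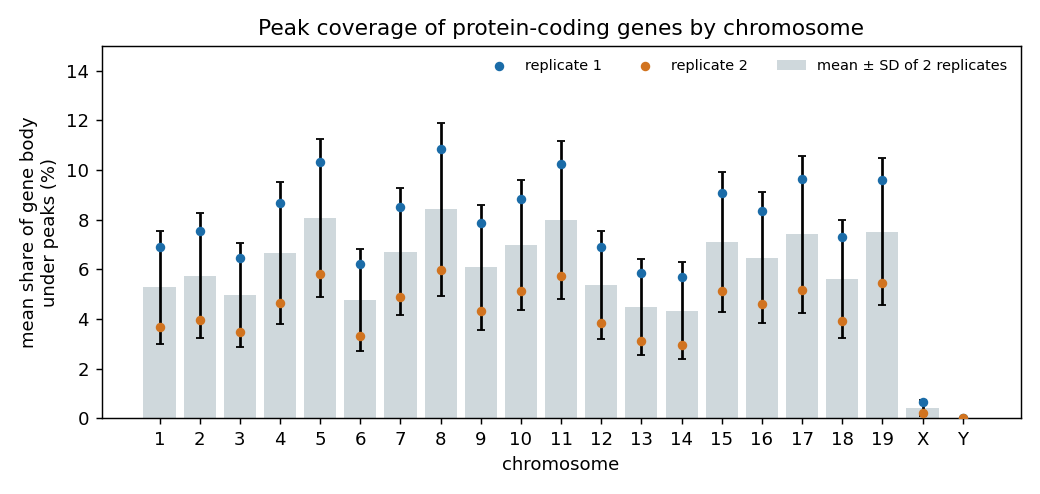
Mean share of the body of protein-coding genes under peaks (y axis, %) for each chromosome (x axis), as bars for the mean of the 2 replicates with SD and a point per replicate. The bar of X stands at 0.429% and that of chromosome 14, the lowest autosome, at 4.34%.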

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

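Chosen only after the result was seen were the test of peak density on X at stricter p, the control on autosomal peaks between replicates, the matching on both position and GC for exons, and the test of highest fold at a like number of peaks.

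Peaks outside the assembled chromosomes were in no comparison of the report and were counted because a signal appeared there. Replicate 1 had 12 peaks and replicate 2 had 22 on unplaced or unlocalised sequences. Of these, 2 in replicate 1 and 8 in replicate 2 lay on 1 unlocalised sequence of chromosome 4, with a highest fold of 6.08 and 7.89. Long intergenic non-coding RNA (lincRNA) genes at least 5 kb from protein-coding genes were also outside the comparisons, and 22 of 4267 held peak bases in both replicates.

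X-linked genes were covered for 0.429 ± 0.319% against 5.97% in length-matched autosomal genes. The genes on X with the highest coverage, named after their values were seen, included Asmt at 20.0 ± 4.76%, the only one marked, the demethylase gene Kdm5c at 15.2 ± 9.41%, Hcfc1 at 14 ± 10.2% and Flna at 10.8 ± 9.89%. Asmt (170672644 to 170678054) was at 16.6% in replicate 1 and 23.4% in replicate 2. Gm21887 (170009659 to 170019281) was likewise higher in replicate 2, at 9.94% and 15.3%. Kdm5c, Hcfc1 and Flna were higher in replicate 1. Whether Asmt and Gm21887 share the dose of other genes on X was not tested. Base composition with gene length is argued against as the whole cause, since after matching on both the difference was -3.94 percentage points (permutation p = 1e-04, the smallest the permutations can give), against -5.54 matched on length alone. A lower dose, from 1 active copy of X per cell against a genome-wide background, stays open. Observed over predicted peak density on X was 0.130 in replicate 2 and 0.242 in replicate 1, below the bound written for it. The prediction was 33.7% and 34.7% of the autosomal density, for a background of both sexes, and with the whole pileup at 0.5 of the autosomal one it was 18.5% and 18.2%, against 4.38% and 8.39% observed. A control with a related model set autosomal floor peaks of replicate 1 against replicate 2. It drew Poisson pileups for the other library, whereas the prediction for X thinned each replicate's own pileups. It predicted that 84.7% of these peaks would be called in replicate 2 and 39.6% were, too high by 2.14 times. That control took the ratio of the 2 background floors as the ratio of depths, which is not known to hold. Its excess may also hold differences between the 2 libraries, so it need not apply to the prediction for X. Applied to the prediction with a background of both sexes, such an excess would bring replicate 1 within the factor of 2 set as the bound. Replicate 2 would stay outside it. For the prediction with the whole pileup at 0.5, the same excess would bring both replicates within the bound, replicate 2 only narrowly. The prediction rests on an assumed dose and on a model that was not tested within a replicate. The bound is therefore not known to be sound, and the shortfall in replicate 2 is not taken to exclude a lower dose. The control between replicates was added after the first outcome was seen. Peak density on X relative to autosomes was 8.39%, 4.57% and 2.98% in replicate 1 at a −log10 p of at least 2, 5 and 8, and 4.38%, 3.98% and 3.15% in replicate 2. No biological explanation was tested, since the design has 1 group.

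Exons of genes were more covered than introns, by 6.09 ± 0.703 times in windows of 300 bp. The GC content of exons is argued against as the whole cause, since the ratio was 4.37 ± 0.435 with intron windows weighted to the GC of exon windows. The position of exons, which lie in more covered genes and nearer gene ends, is a candidate explanation for most of it, since the ratio was 1.66 ± 0.0947 within the same segment of the same gene. With GC matched as well it was 1.48 ± 0.0520, and what remains is open. No biological explanation was tested.

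The 7 cell type lists of epithelium, enterocytes, secretory cells, enteric neurons, endothelium, erythroid cells and leukocytes were covered less than the lists of general cell functions. All 7 were lists called lower, and the lists of smooth muscle at 7.57%, mesenchyme at 6.03%, stem and progenitor cells at 4.03%, interstitial cells of Cajal at 0.244% and mesothelium at 0%, which were not, were left out of the tests, so these speak only for those 7. Peaks of overlapping neighbour genes are argued against, since the ratio of the 2 kinds of list was 35.9 without overlapping genes and 20.4 with all. Dilution of marked cells to near the calling floor stays open. The 71 members of cell type lists with a replicate 1 peak had a median highest fold of 2.70, a difference of -0.601 from length-matched genes, but those held 11.2 peaks on average against 4, and a maximum over fewer peaks is lower, so that test decides nothing. Against genes with a like number of peaks the difference was -0.181 (permutation p = 0.0382). These lists were low in coverage in the same peaks, and peak width was not matched. A lower fold may follow from that alone, so this test does not decide on dilution either. Weaker transcription in all cells would predict the same lower fold, so it stays open too. No biological explanation was tested.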

How the results depend on the processing

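Merging of peaks across gaps of 1 kb, and the stricter and the equal-sized peak sets for the agreement of peak strength, were tests chosen only after the results were seen. No result with a call changed direction in any alternative run. The lower coverage of X-linked genes was past the threshold in each alternative run, with differences from -3.46 to -8.82 percentage points. The lists of spliceosome, cell cycle, ribosomal, proteasome, complex I and zinc finger genes were higher than random lists in each alternative run. Of the single-list results under alternatives, 335 kept their direction and their side of the threshold, 54 lost the call, 1 gained it, and 16 changed direction in lists that were past the threshold in neither setting. The cause was not tested for any value below, except where the alternative itself leaves out peaks, genes or replicates.

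The share of replicate 2 peaks that touched a replicate 1 peak was 30.9% with 50% reciprocal overlap, 62.0% at a −log10 p of at least 5 and 56.1% with equal numbers of peaks. In the last 2 of these settings the rho of peak fold was 0.175 and 0.175, and gene bodies held 96.5% and 96.1% of peak bases, against 96.3% in the authors' replicated list. At a −log10 p of at least 5, 76.4% of pooled peaks were replicated and the rho of covered shares was 0.822. The ratio of the last to the first 5 bins was 5.26 for genes of 3 kb or more, 4.95 at a −log10 p of at least 5, 4.44 with equal numbers of peaks, 4.66 in the replicated list and 3.88 in the pooled list. Marked genes numbered 1519 at a −log10 p of at least 5, 6423 in the pooled list, 5093 and 894 with minimums of 5% and 25%, 1497 without overlapping genes, and 3370 to 5564 with 1 replicate left out. In the pooled list and with 1 replicate left out, coverage in each of 2 replicates was not required. The excess of spliceosome genes in replicate 1 was 4.49 percentage points with equal numbers of peaks.

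Lists past the threshold numbered 15 at a −log10 p of at least 5, 7 without overlapping genes and 10 by the share of marked members, against 25 as reported. List minus random lists, in percentage points, is given for each list whose call changed. At a −log10 p of at least 5 it was -3.18 for endothelium, -3.75 for erythroid, -3.01 for macrophage and leukocyte, -3.72 for pancreas, -3.61 for stomach, -3.86 for lung, kidney and spleen, -3.57 for striated muscle, -3.33 for skin, eye and inner ear, -4.09 for germline and -3.90 for pluripotency. With equal numbers of peaks it was -4.99 for stomach, and with no length minimum -5.89 for stomach. In the replicated list it was -5.59 for macrophage and leukocyte and -7.28 for stomach. In the pooled list it was -10.4 for mesothelium and -6.30 for macrophage and leukocyte, of which mesothelium gained the call. Without overlapping genes, which leaves fewer members, it was -3.57 for intestinal epithelium regulators and markers, -3.97 for enterocyte absorption and brush border, -4.84 for secretory and enteroendocrine lineage, -4.73 for enteric neurons and glia, -4.66 for endothelium, -4.92 for erythroid, -3.39 for macrophage and leukocyte, -5.39 for hepatocyte, -4.57 for pancreas, -5.19 for stomach, -4.502 for lung, kidney and spleen, -4.10 for striated muscle, -3.67 for central nervous system, -4.03 for skin, eye and inner ear, -5.31 for germline, -4.76 for pluripotency, -3.45 for Hox clusters and 9.69 for H3K36 methylation writers, readers and erasers. By the share of marked members it was -13.7 for enterocyte absorption and brush border, -14.3 for enteric neurons and glia, -14.6 for endothelium, -17.0 for erythroid, -14.2 for macrophage and leukocyte, -18.7 for hepatocyte, -16.1 for pancreas, -16.8 for stomach, -16.5 for lung, kidney and spleen, -15.1 for striated muscle, -14.3 for central nervous system, -14.4 for skin, eye and inner ear, -17.3 for germline, -16.5 for pluripotency and -12.4 for Hox clusters. With 1 replicate left out it ran from -7.27 to -4.24 for erythroid, -5.73 to -3.40 for macrophage and leukocyte, -7.67 to -4.39 for pancreas, -7.37 to -4.43 for stomach, -8.07 to -4.54 for lung, kidney and spleen and -7.91 to -4.51 for pluripotency, and these calls were lost without replicate 1.

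Among lists past the threshold in neither setting, list minus random lists changed direction as follows, in percentage points. At a −log10 p of at least 5 it was -0.307 for mesenchyme and -0.0337 for imprinted genes. For Wnt genes it was -0.361 in the replicated list, -0.886 in the pooled list, -0.667 with peaks merged, -3.002 without overlapping genes, -0.156 with unmatched random lists, and from -0.123 to 0.173 with 1 replicate left out. For imprinted genes it was -0.268 in the replicated list and -3.02 without overlapping genes. For Notch genes it was 0.0739 in the pooled list, 3.01 with exons only and 6.96 by the share of marked members. It was 3.45 for Hedgehog genes with exons only, -0.0894 for mesenchyme with unmatched random lists, and 1.20 for stem and progenitor genes by the share of marked members.

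The sequencing depth is unknown. Coverage cannot fall below 0%, so a peak set with lower coverage in the random lists leaves less room below them.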

Other observations

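The gene families, the strongest peaks and the non-coding genes below, and the tests on them, were all chosen after the data were seen.

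Of families of genes sharing the letters of their symbols, the Ddx family of RNA helicases was covered for 25.1 ± 7.501% of gene length on average against 7.76% in length-matched random lists, with 23 of 37 members marked, the highest mean of the families tested. The Mcm replication genes followed at 24.5 ± 8.88% and the Prpf splicing genes at 23.9 ± 9.29%. The Psmd proteasome genes were at 21.2 ± 8.60%, the Rpl genes at 21 ± 5.81% and the Anapc genes of the anaphase-promoting complex at 20.3 ± 5.96%. The Mcm, Prpf, Psmd and Rpl families share members with the cell cycle, spliceosome, proteasome and ribosomal lists. So do other families counted below with lists reported above, such as Zfp and Olfr. Their values repeat those results in part and are not separate support. Eif translation initiation genes were covered for 21.2 ± 5.33% against 6.94% with 30 of 55 marked, Polr polymerase subunit genes for 22.6 ± 7.35% with 19 of 28 marked, and Nup nuclear pore genes for 19.4 ± 7.53% with 14 of 21 marked. Mitochondrial ribosomal Mrpl genes were covered for 15.2 ± 7.59% with 19 of 46 marked. At the other end, Prl, Serpina and Ces genes were at 0%, Serpinb genes at 0.212 ± 0.162% and Clec genes at 0.313 ± 0.168%. Of 251 families of at least 10 genes sharing the letters of their symbols, 48 were higher and 23 lower than random lists after Benjamini-Hochberg adjustment over the families, with an adjusted permutation p of 0.00114 for Ddx, Eif, Polr and Nup, 0.00186 for Mrpl and 0.0102 for Clec.

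Zinc finger genes with Zfp symbols held many of the strongest peaks. Of the 100 peaks with the highest authors' fold, 30 in replicate 1, 27 in replicate 2 and 38 in the replicated list touched such a gene, against 2.02, 2.34 and 2.25 in random draws of 100 peaks (permutation p = 1e-04 in each, the smallest the draws can give). The strongest peak of replicate 1, on chromosome 7 (5028673 to 5033503), had a fold of 8.38 and touched Zfp865 and Ccdc106. The strongest of replicate 2, on chromosome 6 (48596135 to 48598754), had a fold of 8.26 and touched the zinc finger gene Repin1. Peaks at Zfp146 reached 6.76 in replicate 1 and 7.34 in replicate 2, and those at Zfp27 reached 6.52 and 7.12.

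Of the lincRNA genes at least 5 kb from protein-coding genes, 3 of 4267 were marked in both replicates. They included Mir17hg, the host of a microRNA cluster (chromosome 14, 115042879 to 115046727), at 22.3 ± 3.53% and Malat1 at 19.3 ± 0.111%. Among non-coding genes picked by name, the imprinted Meg3 was at 7.76 ± 6.92%, Mirg at 10.7 ± 4.06%, Airn, which overlaps the marked gene Igf2r and cannot be separated from it without strand, at 6.55 ± 3.01%, and Fendrr, a neighbour of Foxf1, at 5.01 ± 4.63%. Gas5 was at 9.02 ± 3.66%, and H19, Hotair, Hottip and Xist were at 0% in both replicates.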
